A study of Sus scrofa with 9 samples.

How the data were processed

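RNA of porcine coronary arterial endothelial cells, the cells that line the coronary artery, was hybridised to 9 Affymetrix porcine arrays, 1 per sample. The labels put 3 arrays in each of 3 groups. Passage 1 cells were the controls, passage 4 cells had been passaged weekly and are called senescent in the labels, and regenerated cells had regrown in vivo after the endothelium was removed and were then cultured without passage. Per the labels' protocols, biotin-labelled cRNA was made from 1 ug of total RNA in the passage 1 and passage 4 groups and from 0.5 to 1 ug in the regenerated group. The RNA input therefore differs with the group and cannot be separated from it. The regenerated arrays were also deposited later, going by the order of their records. Passage differs as well, since the regenerated cells were not passaged and the controls were at passage 1. The labels do not say whether arrays of a group came from separate animals or cultures. The p-values then measure only the spread between these arrays, which may be technical.

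The deposited values are probe set intensities on a linear scale, named by the submitters' processing notes as MAS5 signals. MAS5 summarises the probes of a probe set into 1 signal and usually scales each array. The MAS5 version, the scaling target and detection calls are not given in the sources used here. The mean trimmed by 2% at each end was 500.1 in every array, so the values were taken as already scaled and were not normalized further. The number of arrays, not a read depth, limits the precision. Median signals ran from 86.5 to 109 between arrays.

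The table held 24123 probe sets, of which 124 control probe sets were left out. A probe set was tested if at least 3 of the 9 arrays lay above their own 40th percentile, which left 15299. Values were taken as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. All 9 arrays were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), with 6 residual degrees of freedom and 5.65 prior degrees of freedom. The tests were two-sided with Benjamini-Hochberg adjustment over the tested probe sets of a comparison, and an adjusted p under 0.05 counted as past the threshold. The 3 comparisons were passage 4 against passage 1, regenerated against passage 1, and passage 4 against regenerated. The last one tests the difference between the other comparisons, because the control cancels.

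The platform annotation gave 1 gene symbol to 10099 probe sets, several to 198 and none to 13826. Entrez identifiers of 9989 of the named probe sets were found in a table of RefSeq genes of the assembly Sscrofa11.1, which changed 0 symbols. No probe set with several symbols was named. Named probe sets that were tested numbered 7671, for 5494 genes. No genome build is named in the files, so no coordinates are printed. Where a gene had several probe sets, lists used the one with the highest mean over the 9 arrays, and other probe sets of a gene can differ from it.

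Before the data were examined, 29 gene lists were fixed, covering endothelial functions, senescence, inflammation, metabolism and markers of other cell types. Of these, 28 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its p-values on the 6 residual degrees of freedom, far fewer than with the preset. For fibroblast markers in regenerated cells the estimated correlation was -0.08, below the preset, yet the camera p went from 5.98e-05 to 0.00573. A call lost with an estimated correlation therefore need not be due to correlation between the genes. The lists overlap in part, so they are not independent of each other. Genes were named by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among named probe sets past the threshold whose 3 arrays all lie on the same side of the 3 control arrays. It adds up to 3 members past the threshold from each list that passed camera, and a fixed panel of endothelial, senescence and inflammatory genes given whatever their result. For passage 4 against regenerated it takes 5 rises and 5 falls. Members of a fixed list may also be named with their values. In the panel, CDKN2A, MKI67 and COL1A1 had no probe set of that symbol, that of PTPRC was below the filter, and a further panel gene is not reported here.

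Bacterial transcripts added to the RNA before labelling (dap and thr) carry probe sets at both ends, and their 5' to 3' signal difference divided the arrays into 2 kinds. This division was found after the data were seen and does not use any measured outcome. Passage 1 array 1 and the 3 passage 4 arrays were of 1 kind, and passage 1 arrays 2 and 3 and the 3 regenerated arrays of the other. A fit with this division as a block has 5 residual degrees of freedom and equals comparisons within each kind. Passage 4 is then compared with passage 1 array 1 alone, and regenerated with passage 1 arrays 2 and 3. No array of passage 4 shares its kind with a regenerated array, so passage 4 and regenerated are then linked only through the passage 1 arrays.

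The procedure was tested on simulated data for passage 4 against passage 1, with 15299 probe sets in 10 simulated sets of arrays and 200 changed probe sets in each. It recovered 41.3% of changes of 1 log2 unit, 94.2% of changes of 2 and 99.5% of changes of 3, and 5.47% of its calls were unchanged probe sets. A list shifted by 0.5 log2 units passed in 10 of 10 sets, and 1 of 270 unshifted lists passed. The simulated genes were drawn independently of each other and without the division by labelling. In the data the estimated inter-gene correlation was 0.40 for interferon response and 0.64 for ribosomal protein genes. The share of 1 in 270 therefore does not carry over to the lists in these data. Alternatives tried were other pseudocounts, normalizations and filters, fits of only the groups compared, no intensity trend, array weights, a fold threshold of 2, the replicate number as a block, each array left out in turn and, for lists, the mean of all probe sets of a gene. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.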

Results

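The expression of 15299 probe sets was compared among 3 groups of 3 arrays each: endothelial cells of the pig coronary artery at passage 1, at passage 4, and regenerated in vivo after denudation of the vessel. Passage 4 cells are called senescent in the labels, after serial passaging in vitro. Regenerated cells were scraped from the vessel and cultured without passage. Within groups, arrays correlated with r from 0.937 to 0.974 across probe sets, and between groups with r from 0.898 to 0.946. Probe sets of an array are not independent replicates, so these values describe likeness only.

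The bacterial spike-in transcripts dap and thr differed between arrays in how far the labelled cRNA reached towards the 5' end. The mean log2 difference of 5' and 3' signal was -2.03 in passage 1 array 1 and -2.12, -1.78 and -1.84 in the passage 4 arrays. It was -5.49 and -4.57 in passage 1 arrays 2 and 3 and -4.68, -4.91 and -5.29 in the regenerated arrays. The largest gap between neighbouring arrays was 2.45 and the next 0.38. For the pig's own Gapdh transcript the difference was -1.07 and -1.52 in regenerated arrays 2 and 3, -0.02 in regenerated array 1, and from 0.14 to 0.46 in the other 6 arrays. For actin it was -1.66, -2.16 and -2.78 in the regenerated arrays and -1.72 and -1.38 in passage 1 arrays 2 and 3. For ef1a it was -0.93, -1.53 and -2.26 in the regenerated arrays and -0.80 and -0.42 in those passage 1 arrays. The signal of 28S ribosomal RNA was 8902 ± 1080 at passage 4, 3254 ± 2320 at passage 1 and 2548 ± 972 in regenerated cells (SD, n = 3). Values within each kind of array are therefore given for the named genes and lists of each comparison whose calls were lost there, and for the counts.

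**Figure D1:**
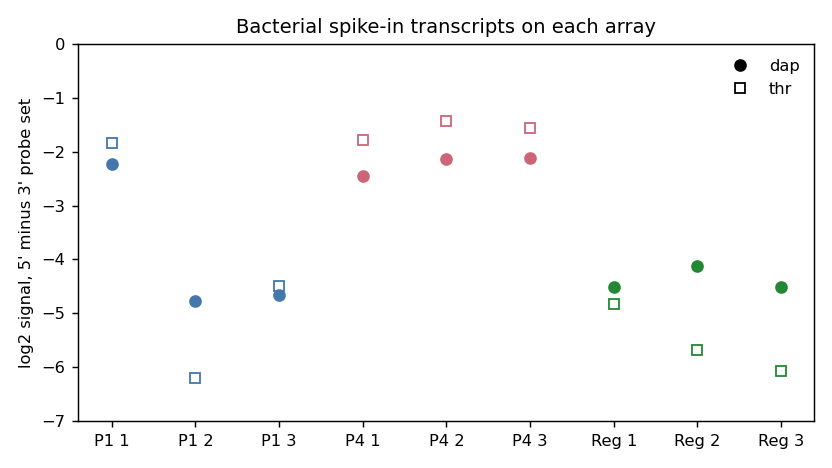
Difference of log2 signal between the 5' and 3' probe sets of 2 bacterial spike-in transcripts (circles dap, squares thr) on each of the 9 arrays, with groups in colour. Passage 1 array 1 lies with the passage 4 arrays, at a mean of -2.03, and passage 1 arrays 2 and 3 lie with the regenerated arrays.

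Cells at passage 4 had lower transcript levels of interferon response genes and of inflammatory and NF-kB targets than cells at passage 1. Of these genes 14 of 27 and 10 of 32 fell past the threshold, and both lists passed camera, but not with an estimated correlation (adjusted p = 0.133 for each). F3, which encodes tissue factor, the starter of the coagulation cascade, fell from between 635 and 994 in the 3 passage 1 arrays to 27.6 ± 18.9 (SD, n = 3), a log2 change of -4.38 (SE 0.42, adjusted p = 0.000591). IL6, a proinflammatory cytokine, fell from 2355 ± 1240 to 202 ± 68.6 (log2 -3.34). Genes of the cell cycle were higher at passage 4 in 49 of 50 cases, with 14 past the threshold (adjusted p = 0.133 with an estimated correlation). EPB41L3, a membrane skeleton protein, rose from 105 ± 40.2 to 3561 ± 561, by 4.94 on the log2 scale (SE 0.37, adjusted p = 0.000246). In all, 733 of 15299 probe sets passed the threshold, 415 upward and 318 downward, and 619 of them also changed at least 2-fold.

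Other large rises at passage 4 were those of STMN2, a microtubule regulator known from neurons (log2 5.09, SE 0.64), and ALDH1A1, a retinaldehyde dehydrogenase (4.95, SE 0.63). Both genes had another probe set that rose as well. The secretory granule protein gene SCG2 rose by 4.79 (SE 1.06), the cytokine gene IL7 by 3.21 (SE 0.53) and the GABA receptor subunit gene GABRA4 by 3.14 (SE 0.56). SCG2 was also at 3045 in regenerated array 3, against 56.0 and 138 in the other regenerated arrays. WDR1 and ACADVL passed with log2 changes of 3.55 and 3.47, each on a dimmer probe set, while their brightest probe sets were at -0.07 and -0.16 and did not pass. For these dimmer probe sets passage 1 array 1 stood at 697 and 379, against 23.7 or less in the other passage 1 arrays. Among the falls, CSF2, encoding a granulocyte and macrophage growth factor, changed by -4.41 (SE 0.70), although its passage 1 arrays spread from 1204 to 8910. The complement gene C1R changed by -3.77 (SE 0.45), the growth factor binding protein gene IGFBP2 by -3.43 (SE 0.53) and the chemokine gene CCL8 by -3.42 (SE 0.62). SAA2, an acute-phase protein gene, changed by -3.78 (SE 0.31), while its brighter probe set was at 0.69 and did not pass. Within the kind of labelling SCG2, IL7 and GABRA4 were at 5.03, 2.86 and 2.50, and CSF2, IGFBP2 and CCL8 at -3.97, -3.18 and -2.65, with adjusted p from 0.0789 to 0.193, so none of these passed there. WDR1 and ACADVL were there at 0.77 and 0.90 (adjusted p = 0.36 and 0.625).

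Of 27 measured interferon response genes, 14 fell and 0 rose, and 24 fell when adjusted over the list alone. All 27 were lower, with a median log2 change of -1.37 (camera adjusted p = 2.35e-18; adjusted p = 0.133 with an estimated correlation). IRF7, a transcription factor of the interferon response, changed by -2.92 (SE 0.31), and the antiviral genes RSAD2 and DDX60 by -2.58 and -2.17. Inflammatory and NF-kB targets had a median of -0.91, with 10 of 32 falling, or 20 with 1 rising adjusted over the list alone (camera adjusted p = 8.09e-11; adjusted p = 0.133 with an estimated correlation). SELE, which encodes E-selectin, an endothelial receptor for leukocytes, fell from 5151 ± 2400 to 435 ± 277 (SD, n = 3). Of 13 MHC class I and II genes 6 fell, or 9 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 7.51e-08; adjusted p = 0.133 with an estimated correlation). The class II genes SLA-DRA, SLA-DQB1 and CD74 changed by -3.62, -3.26 and -2.34. Passage 1 array 3 stood at 692 for CD74, against 162 and 177 in the other passage 1 arrays, and at 940 for SLA-DRA, against 292 and 455. In that array the median of 8 leukocyte markers lay 0.62 above the passage 1 mean. Leukocyte markers had a median change of -0.50 at passage 4 (camera adjusted p = 0.17), and did not pass without passage 1 array 3 either. They passed without passage 1 array 2 (-0.68, camera adjusted p = 0.0483), where passage 1 array 3 weighs more. The MHC list passed at passage 4 with each array left out in turn, passage 1 array 3 among them. Within the kind of labelling RSAD2, SELE, SLA-DRA, SLA-DQB1 and CD74 were at -2.99, -2.90, -2.87, -2.39 and -1.64, with adjusted p from 0.0524 to 0.283, and none passed.

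Cell cycle genes had a median log2 change of 0.70, and 14 of 50 rose with 0 falling, or 26 adjusted over the list alone (camera adjusted p = 1.64e-20; adjusted p = 0.133 with an estimated correlation). CENPF, a kinetochore protein gene, rose by 1.91 (SE 0.31), TYMS, for thymidylate synthase, by 1.79 (SE 0.45), and CCNA2, for cyclin A2, by 1.52 (SE 0.28). Against passage 1 array 1 alone, the array with the same kind of labelling, the median was 0.89 and 50 of 50 genes were higher. For TYMS that array stood at 2303, against 665 and 727 in the other passage 1 arrays, and its change within the kind was 0.65 (adjusted p = 0.582). CENPF and CCNA2 were there at 1.96 and 1.12 and did not pass either (adjusted p = 0.0674 and 0.196). All 7 genes of nuclear factors lost in senescence, a list that includes lamin and chromatin proteins, were also higher (median 0.70). None of the 7 passed among all probe sets, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.274 with an estimated correlation).

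Endothelial identity genes moved in both directions, with 2 of 27 falling and 1 rising, or 5 falling adjusted over the list alone, and a median of -0.35 (camera adjusted p = 0.00858; adjusted p = 0.339 with an estimated correlation). LMO2, a transcription cofactor, changed by -1.92, and TSPAN7, a tetraspanin, by 2.20. NOS3, the gene of endothelial nitric oxide synthase, fell from 1612 ± 379 to 809 ± 178 (SD, n = 3), a log2 change of -0.97 (SE 0.25, adjusted p = 0.045). That call was lost in 12 of the 20 alternatives to the main fit. Within its kind of labelling the change of NOS3 was -0.55 (adjusted p = 0.48), and that of the identity list was -0.18 (camera adjusted p = 0.514). Without passage 1 array 3 the identity list was at -0.22 and did not pass (adjusted p = 0.0911), and without passage 1 array 1 it was at -0.55 (adjusted p = 0.00414). The endothelial adhesion genes PECAM1 and CDH5 were at log2 differences of 0.10 and -0.08, and neither passed. Of 18 shear-stress and quiescence regulators 4 fell, or 7 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 1.92e-05; adjusted p = 0.149 with an estimated correlation). Among them were TXNIP, an inhibitor of thioredoxin (-2.53), and ITPR3, a calcium release channel (-1.19). Matrix proteases and inhibitors had 4 of 18 falling, or 6 adjusted over the list alone, and a median of -0.53 (camera adjusted p = 0.000192; adjusted p = 0.133 with an estimated correlation). MMP2 and PLAU changed by -1.82 and -1.12, and TIMP1 fell from 9204 ± 1220 to 4640 ± 891. Within the kind of labelling LMO2, TXNIP, ITPR3, MMP2, PLAU and TIMP1 were at -2.05, -1.60, -0.88, -1.78, -0.76 and -0.85, with adjusted p from 0.0549 to 0.348, and none passed. The medians of the shear-stress and protease lists were there -0.38 and -0.29 (adjusted p = 0.03 and 0.0267).

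Glycolysis and hypoxia genes had a median of -0.13 with 4 of 30 falling, or 6 adjusted over the list alone (camera adjusted p = 0.00858; adjusted p = 0.247 with an estimated correlation). They included the glucose transporter genes SLC2A3 (-1.78) and SLC2A1 (-1.17) and EPAS1 (-1.44), for a hypoxia-inducible factor. Without passage 1 array 1 that list did not pass (adjusted p = 0.0777), without passage 4 array 2 its median was -0.23, and within the kind of labelling -0.21. Immediate early genes had a median of -0.38, with 3 of 21 falling and 1 rising, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.00889; adjusted p = 0.247 with an estimated correlation). ZFP36 and PPP1R15A changed by -1.70 and -1.10, while JUN rose by 1.42. The immediate early list was at -0.25 and did not pass with a stricter filter on dim probe sets (adjusted p = 0.0808), and was at -0.59 and -0.23 without passage 1 array 1 or 3. Ribosomal protein genes were higher in 55 of 62 cases with a median of 0.09, and RPL37 alone passed, also when adjusted over the list alone (camera adjusted p = 0.00889; adjusted p = 0.758 with an estimated correlation). That list did not pass without passage 4 array 1 (median 0.02, adjusted p = 0.319) or passage 1 array 3 (0.07, adjusted p = 0.165), nor with median centring (0.05, adjusted p = 0.0523). It was at 0.04 with quantile normalization and 0.16 without passage 4 array 2. Proteasome genes had a median of -0.14 and 3 of 40 fell, also when adjusted over the list alone (camera adjusted p = 0.0283; adjusted p = 0.574 with an estimated correlation). These were PSMA6 and the genes PSME1 and PSME2, which encode an interferon-induced activator. The proteasome list did not pass without passage 1 array 3 (median -0.05, adjusted p = 0.384) or passage 4 array 2 (-0.12, adjusted p = 0.0953), nor with quantile normalization (adjusted p = 0.0929) or no intensity trend (adjusted p = 0.0614). With fry in place of camera the identity, nuclear factor, ribosomal and proteasome lists did not pass. Within the kind of labelling 3 of these calls were lost, with adjusted p of 0.253 for immediate early, 0.645 for ribosomal and 0.937 for proteasome genes, whose median there was 0.08. EPAS1, SLC2A1, ZFP36, PPP1R15A and JUN were there at -1.71, -0.84, -1.04, -0.51 and 0.64, RPL37 at 0.99, and PSME2, PSME1 and PSMA6 at -0.84, -0.80 and -0.47. Their adjusted p ran from 0.0661 to 0.525, and none passed.

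In the fixed panel, CDKN1A, the gene of the cell cycle inhibitor p21, stood at 4960 ± 1140 at passage 1 and 3939 ± 119 at passage 4, a log2 change of -0.31 (adjusted p = 0.417). TOP2A, a gene of dividing cells, was at 0.63 (adjusted p = 0.0938) and SOD2, for the mitochondrial superoxide dismutase, at -1.26 (adjusted p = 0.0757), and neither passed. FABP4, a fatty acid binding protein gene, was dim in both groups, at 17.8 ± 2.96 and 1.58 ± 0.854 (adjusted p = 0.0853). CXCL8, VCAM1, PTGS1, VWF and MMP7 did not pass, with log2 changes of -0.26, 0.05, 0.18, -0.88 and 0.14. VWF was near the floor, at 35.8 ± 46.7 at passage 1 and 6.31 ± 5.33 at passage 4, and MMP7 ran from 3.0 to 183 among passage 1 arrays. These 2 probe sets can therefore say little about a change. Smooth muscle markers had a median of 0.12, with 2 of 15 falling, or 2 falling and 3 rising adjusted over the list alone (camera adjusted p = 0.426). Fibroblast markers had a median of 0.17 with 0 of 10 past the threshold, or 1 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.426). ACTA2, for smooth muscle actin, ranged from 196 to 13189 among passage 1 arrays, and was at -0.07 (adjusted p = 0.984), or -2.85 within the kind of labelling (adjusted p = 0.443). TAGLN, another smooth muscle marker, was at -0.40 (adjusted p = 0.453). Within the kind of labelling the medians of the smooth muscle and fibroblast lists were -0.30 and 0.56. The count of 733 became 150 within the kind of labelling, 71 upward and 79 downward, of which 126 were also among the 733, and 11 of the 43 named genes past the threshold stayed past it. The median standard error was there 0.348 against 0.266, with 1 passage 1 array to compare with. All 733 probe sets kept their sign there, so a call lost there need not mean a smaller change. The count of 733 was 244 without passage 1 array 2 and 1403 without passage 1 array 1. It was 310, 300 and 262 without passage 4 array 1, 2 or 3.

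**Figure D2:**
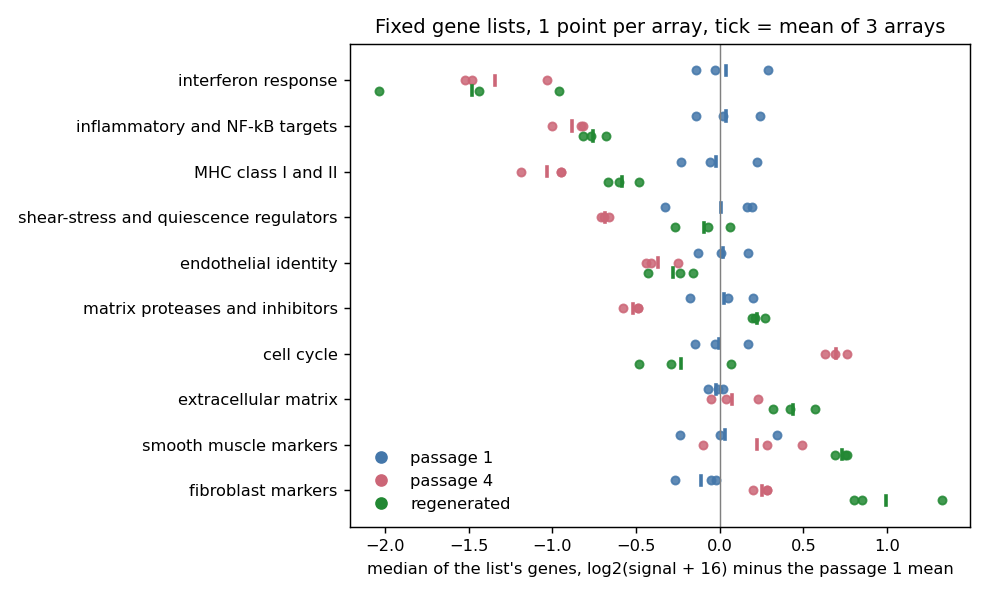
Median log2(signal + 16) over the genes of 10 fixed lists, less the passage 1 mean, with 1 point per array and a tick at the mean of each group of 3. Interferon response lies from -1.52 to -1.03 at passage 4 and from -2.04 to -0.96 in regenerated cells, and cell cycle from 0.63 to 0.76 at passage 4.

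Regenerated cells had higher levels of extracellular matrix genes and lower levels of interferon response genes and of inflammatory and NF-kB targets than passage 1 cells. Of these genes 10 of 31 rose with 1 falling, and 18 of 27 and 11 of 32 fell. The lists passed camera, but not with an estimated correlation (adjusted p of 0.136, 0.156 and 0.156). PMEPA1, a gene induced by TGF-beta, rose from 239 ± 149 to 4137 ± 507 (SD, n = 3), a log2 change of 4.20 (SE 0.39, adjusted p = 0.000319). The list of endothelial-to-mesenchymal transition genes and TGF-beta targets did not pass (median 0.18, camera adjusted p = 0.195; adjusted p = 0.527 with an estimated correlation). Of its 17 genes 1 rose, or 2 with 1 falling adjusted over the list alone. ASPN, for the matrix proteoglycan asporin, rose from 141 ± 102 to 1748 ± 393 (3.66, SE 0.49). FABP4 rose from 17.8 ± 2.96 to 208 ± 57.6 (2.70, SE 0.28, adjusted p = 0.00068). IL6 fell from 2355 ± 1240 to 188 ± 38.8 (-3.40, SE 0.37). In all, 840 of 15299 probe sets passed, 456 upward and 384 downward, and 638 of them changed at least 2-fold.

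Other large rises were those of SLC1A1, a glutamate transporter gene (4.47, SE 0.41), MAP2K6, a kinase of the p38 pathway (4.19, SE 0.44), and TMEM117, a membrane protein gene (4.10, SE 0.64). The matrix gene MGP rose by 3.47 (SE 0.71), with passage 1 array 3 at 3676 against 390 or less in the other passage 1 arrays. The proteoglycan gene LUM rose by 3.50 (SE 0.87), but regenerated array 2 stood at 30.1 against 660 and 1015 in the others. FNTA rose by 3.37 on a dim probe set, while its brightest probe set fell by 0.61 (adjusted p = 0.0394). Large falls were those of CSF2 (-4.34, SE 0.70), CCL8 (-3.35, SE 0.62), the RNA sensor gene DDX58 (-3.23, SE 0.43), and the keratin gene KRT8 (-3.14, SE 0.54). SERPINB2, for plasminogen activator inhibitor 2, changed by -3.12 (SE 0.43). The chemokine gene AMCF-II changed by -3.49 (SE 0.75), while its brighter probe set was at -0.14 and did not pass. Within the kind of labelling LUM and AMCF-II were at 3.31 and -2.88 and did not pass (adjusted p = 0.0742 and 0.0504).

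Of 27 interferon response genes 18 fell and 0 rose, or 24 adjusted over the list alone, and the median was -1.45 (camera adjusted p = 1.21e-18; adjusted p = 0.156 with an estimated correlation). DDX60, USP18 and IRF7 changed by -3.14, -2.63 and -2.51. Inflammatory and NF-kB targets had 11 of 32 falling, or 16 adjusted over the list alone with 1 rising, and a median of -0.73 (camera adjusted p = 3.52e-06; adjusted p = 0.156 with an estimated correlation). SELE fell to 614 ± 405 (log2 -3.11). Among 13 MHC class I and II genes 2 fell, or 5 adjusted over the list alone, with a median of -0.79 (camera adjusted p = 0.00143; adjusted p = 0.247 with an estimated correlation). These were CD74 (-2.17) and the class I gene SLA-3 (-1.25). The MHC median was -0.47 with a stricter filter on dim probe sets, and -0.43 and -0.52 without passage 1 array 3 or regenerated array 1, and the list passed in each. Proteasome genes had a median of -0.21, with 9 of 40 falling, also when adjusted over the list alone (camera adjusted p = 3.32e-05; adjusted p = 0.34 with an estimated correlation), and of -0.09 without passage 1 array 3. PSMB8 and PSMB10, subunits of the interferon-induced immunoproteasome, changed by -2.07 and -1.28, and PSMF1, for a proteasome inhibitor, by -1.73, while its dimmer probe set was at -0.79 and did not pass.

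Extracellular matrix genes had a median of 0.34, with 10 of 31 rising and VCAN falling, or 11 and 1 adjusted over the list alone (camera adjusted p = 4.08e-05; adjusted p = 0.136 with an estimated correlation). Besides ASPN, LUM and MGP, the collagen genes COL5A1 and COL8A1 rose by 1.03 and 0.73, THBS2, for thrombospondin 2, by 2.47, and LOXL1, for a matrix crosslinking enzyme, by 0.95. Of 4 probe sets each, 2 of COL5A1 and 1 of COL8A1 rose. In regenerated arrays 2 and 3 the 5' signal of the pig's own transcripts was also lower relative to the 3' signal. For Gapdh, actin and ef1a it was lower there than in any passage 1 array. That difference applies to those arrays in every list described here, and less to regenerated array 1. Actin in regenerated array 1, at -1.66, lay above passage 1 array 2, at -1.72. Its ef1a, at -0.93, and its Gapdh lay below every passage 1 array, so that array is not free of the difference. In regenerated array 1, where Gapdh was at -0.02, the extracellular matrix, smooth muscle and fibroblast medians lay 0.42, 0.76 and 1.33 above the passage 1 mean. Fibroblast and smooth muscle markers were higher in the same arrays. Leukocyte markers were at a median of -0.34 with 2 of 8 higher (camera adjusted p = 0.708), and epithelial and mesothelial markers at -0.27 with 2 of 7 higher and KRT8 falling (adjusted p = 0.247). Of 10 fibroblast markers 4 rose, or 5 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 0.000279; adjusted p = 0.136 with an estimated correlation). That median was 0.33 without a filter on dim probe sets, 2.89 with a stricter one and 0.69 within the kind of labelling or without passage 1 array 1, and the list passed in each. FAP, a surface protease gene, rose by 3.25 (SE 0.45) and THY1 by 2.89 (SE 0.42), while COL1A2 and DCN, also in that list, were at 0.08 and 0.23 and did not pass. FAP lay below the 40th percentile in every passage 1 and passage 4 array, so it was tested only through the regenerated arrays. The filter can thus admit a marker through the group where it is high, and the steps of the median with the filter do not measure stability. The median of 0.33 without a filter (camera adjusted p = 0.0172) is free of that selection. Of the 10 fibroblast markers 6 also stand in other lists. Of 15 smooth muscle markers 14 were higher and 3 rose, or 4 adjusted over the list alone, with a median of 0.64 (camera adjusted p = 4.59e-05; adjusted p = 0.215 with an estimated correlation), or 0.39 without the filter. SYNM, FHL1 and SMTN rose by 1.10, 0.96 and 0.89 (SMTN within the kind of labelling 0.78, adjusted p = 0.0809), and TAGLN, also in that list, was at -0.04 and did not pass. ACTA2 stood at 13730 ± 4630 in regenerated and 5301 ± 6930 in passage 1 arrays (log2 2.79, adjusted p = 0.232). Within the kind of labelling ACTA2 was at 4.18 and did not pass (adjusted p = 0.0582).

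Of 9 cardiac and adipose markers only NPPB, for a natriuretic peptide, rose, from 51.4 ± 10.1 to 409 ± 229 (SE of the log2 change 0.39), also when adjusted over the list alone, and the list's median was 0.35 (camera adjusted p = 0.0407; adjusted p = 0.215 with an estimated correlation). That list did not pass without passage 1 array 2 or 3 or regenerated array 3, with adjusted p of 0.0625, 0.131 and 0.0697. Nor did it with quantile normalization (0.0594), a pseudocount of 4 (0.05), no filter (0.133) or a stricter filter on dim probe sets, where its median was 0.05 (0.769). Glycolysis and hypoxia genes had 3 of 30 falling, also when adjusted over the list alone, and a median of -0.27 (camera adjusted p = 0.00282; adjusted p = 0.215 with an estimated correlation), or -0.16 without regenerated array 2. ADM, for the vasodilator adrenomedullin, changed by -2.75, SLC2A3 by -1.41 and HILPDA, a lipid droplet protein gene, by -0.92. HILPDA was at -1.12 on its dimmer probe set, which did not pass, and at -0.72 within the kind of labelling (adjusted p = 0.0935). Endothelial identity genes had a median of -0.20 (camera adjusted p = 0.101), or -0.35 without regenerated array 1 (adjusted p = 0.0353), and NOS3 was at -0.23 (adjusted p = 0.635). PECAM1 was at -0.19 and did not pass, although its other probe set fell, and CDH5 was at 0.06 and did not pass. CDKN1A, TOP2A, SOD2, CXCL8, VCAM1, PTGS1, VWF and MMP7 did not pass, with log2 changes of 0.33, -0.28, -1.33, 0.05, -0.07, 0.37, 0.43 and 1.61. VWF was dim in regenerated cells too, at 42.0 ± 23.4. Against passage 1 arrays 2 and 3 alone, of the same kind of labelling, 926 probe sets passed, of which 632 were among the 840, and 29 of 33 named genes stayed past the threshold. The count was 291 without regenerated array 2, 345 without regenerated array 3 and 513 without passage 1 array 3, and it was 479 with only the 6 arrays of these groups in the fit.

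**Figure D3:**
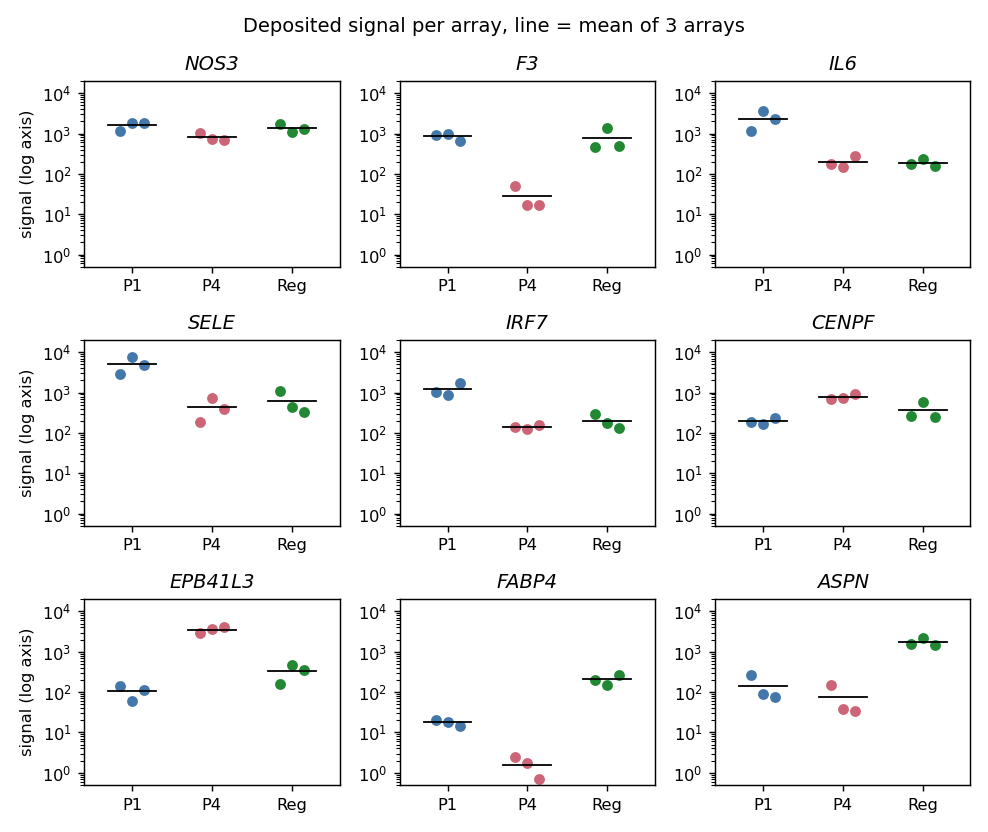
Deposited signal of 9 named genes on a log axis, with 1 point per array (P1 passage 1, P4 passage 4, Reg regenerated) and a line at the mean of 3 arrays. F3 lies from 16.6 to 49.4 at passage 4 against 454 or more in the other groups, and FABP4 lies from 154 to 269 in regenerated cells.

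The comparisons with passage 1 shared falls more than rises. Both test groups fell for 121 probe sets, where independent lists of those sizes would share 7.98, and both rose for 76, against 12.4. Opposite calls numbered 11, against 19.9. With unchanged groups simulated against the same 3 controls, the mean overlap was 0.01 upward and 0 downward over 100 draws, as unchanged groups give almost no calls. Over all probe sets the fold changes had the same sign in 57.7%, against 66.7% in that simulation and 47.2% with the kinds of labelling as a block. Probe sets that fell in both included CSF2, CCL8, IL6, IRF7, DDX60, SELE and C1R. For such shared falls, high levels in the passage 1 arrays and low levels in both test groups cannot be told apart. Both comparisons rest on passage 1 as the only reference. The log2 fold changes correlated with r = 0.276 across probe sets, against 0.499 in the simulation, where sharing controls is the sole source. Their covariance was 0.0979, against 0.0454 simulated. With the kinds of labelling as a block the comparisons use different control arrays, and r was 0.115 and the covariance 0.0453. The 3 control arrays cannot be divided into sets of at least 2, so part of the overlap may come from the shared controls. With that block 48 fell in both and 23 rose, where independent lists would share 2.02 and 2.48, and 7 were opposite.

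**Figure D4:**
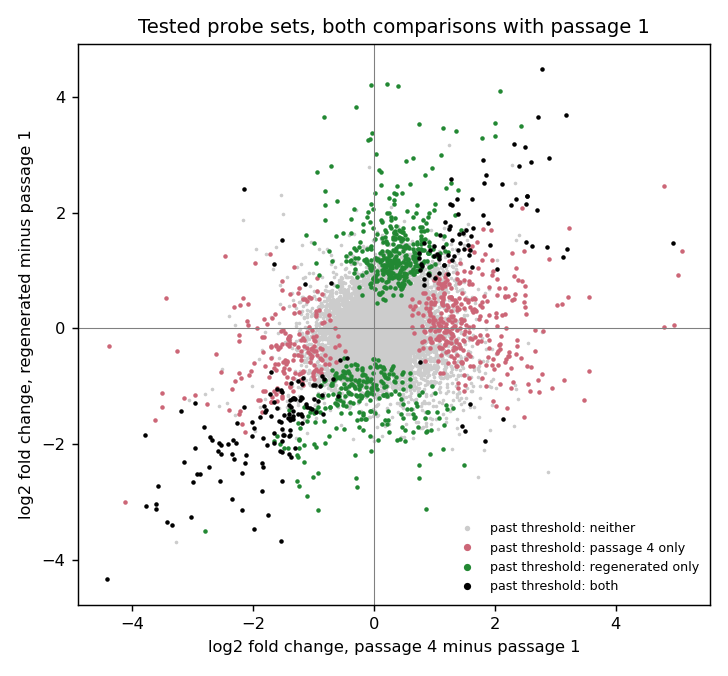
Log2 fold change against passage 1 of each tested probe set, passage 4 on the horizontal and regenerated on the vertical axis, coloured by which comparison it passed. The 121 probe sets that fell in both lie at lower left and the 76 that rose in both at upper right.

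Passage 4 and regenerated cells were compared directly. Cell cycle genes were higher at passage 4 in 31 of 50 cases past the threshold, with 1 lower (adjusted p = 0.187 with an estimated correlation). Extracellular matrix genes had 7 of 31 lower and 3 higher, a list call lost with an estimated correlation (adjusted p = 0.251) and with the kinds of labelling as a block (adjusted p = 0.06). POSTN, for the matrix protein periostin, was at 6387 ± 2450 at passage 4 and 524 ± 845 in regenerated cells (SD, n = 3), a log2 difference of 5.35 (SE 1.04, adjusted p = 0.00809), although regenerated array 2 stood at 1500. ALDH1A1 was higher at passage 4 by 4.90 and STMN2 by 4.10 on its brighter probe set, and ACADVL and WDR1 by 4.71 and 4.29 on their dimmer probe sets. The brightest probe sets of ACADVL and WDR1 were at -0.11 and -0.19 and did not pass, and with the kinds of labelling as a block the dimmer ones were at 0.85 and 0.11 (adjusted p = 0.618 and 0.924). ASPN was lower at passage 4 by a log2 difference of -4.49 (SE 0.49, adjusted p = 0.000742), and PMEPA1, F3, IGFBP2 and MAP2K6 by -4.25, -4.07, -3.96 and -3.78. With that block POSTN, ALDH1A1 and STMN2 were at 4.72, 2.47 and 4.31 and PMEPA1, F3, IGFBP2 and MAP2K6 at -2.80, -4.31, -3.59 and -3.50, with adjusted p from 0.0504 to 0.231, and none passed. In all, 1912 probe sets passed, 1246 higher and 666 lower at passage 4, and 1401 of them differed at least 2-fold. The higher ones made up 65.2%, against 59.7% with quantile normalization and 56.4% with median centring of the arrays.

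Of 50 cell cycle genes 31 were higher at passage 4 and 1 was lower, or 41 and 1 adjusted over the list alone, with a median of 0.94 (camera adjusted p = 3.48e-19; adjusted p = 0.187 with an estimated correlation). Nuclear factors lost in senescence had 4 of 7 higher, or 7 adjusted over the list alone, and a median of 1.09 (camera adjusted p = 0.000186; adjusted p = 0.252 with an estimated correlation). Proteasome genes had 5 of 40 higher, also when adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.0213; adjusted p = 0.596 with an estimated correlation), and that call was lost without regenerated array 2 (adjusted p = 0.0561), with fry (0.125) and with the mean of all probe sets of a gene (0.0847). The proteasome median was 0.14 with quantile normalization and 0.12 with array weights, and from 0.11 to 0.17 with each of the other arrays of these groups left out in turn. With median centring of the arrays the proteasome median was -0.00743 and the list did not pass, while with the kinds of labelling as a block it was 0.41 with 36 of 40 genes higher (adjusted p = 0.000347). Lower at passage 4 were 4 of 10 fibroblast markers with 1 higher, or 5 and 2 adjusted over the list alone (median -0.91, camera adjusted p = 0.0162). Smooth muscle markers had 3 of 15 lower, or 5 adjusted over the list alone (median -0.42, camera adjusted p = 0.00426), and cardiac and adipose markers 4 of 9, also when adjusted over the list alone (median -0.72, camera adjusted p = 0.00233). With an estimated correlation the adjusted p of these marker lists was 0.187, 0.374 and 0.187. Without a filter on dim probe sets the fibroblast median was -0.37 and did not pass (adjusted p = 0.0993), and with a stricter filter it was -2.35. As FAP was tested only through its high regenerated arrays, these steps do not measure how stable the call is. The cardiac and adipose median was -0.35 without the filter and, with the stricter one, -0.94 without passing (adjusted p = 0.231). With the labelling block the nuclear factor and smooth muscle medians were 1.89 and -0.77.

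Extracellular matrix genes had 7 of 31 lower and 3 higher at passage 4, or 10 and 5 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.0145; adjusted p = 0.251 with an estimated correlation). With the mean of all probe sets of a gene the median was -0.11 and the list did not pass (adjusted p = 0.27). The higher ones were POSTN, THBS1 and LOX. With the kinds of labelling as a block THBS1 and LOX went from 2.08 and 1.46 to 0.32 and -0.01 (adjusted p = 0.837 and 0.994), and another THBS1 probe set was lower at passage 4 (-0.90, adjusted p = 0.0196). Matrix proteases and inhibitors had 7 of 18 lower, or 8 adjusted over the list alone with 1 higher (median -0.83, camera adjusted p = 0.000277; adjusted p = 0.187 with an estimated correlation). Shear-stress and quiescence regulators had 6 of 18 lower, or 9 adjusted over the list alone (median -0.54, camera adjusted p = 0.000385; adjusted p = 0.251 with an estimated correlation). The interferon response list did not pass, with 1 of 27 genes higher (median 0.24, camera adjusted p = 0.316, or 0.44 and 0.0185 without regenerated array 1), nor did inflammatory and NF-kB targets (median -0.08, camera adjusted p = 0.515). With the kinds of labelling as a block 35 probe sets passed, 11 higher and 24 lower, of which 29 were among the 1912, and ASPN alone of the 10 named genes stayed past the threshold. The median standard error was then 0.444 against 0.266, and the fibroblast, extracellular matrix, protease and shear-stress lists did not pass (medians of -0.55, -0.11, -0.24 and -0.27, adjusted p of 0.0805, 0.06, 0.0761 and 0.452). The count was 895 and 943 without regenerated array 3 or 2, and 1043, 1033 and 983 without passage 4 array 1, 2 or 3.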

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

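The tests of labelling and of other cell types were chosen after the results were seen, while the splits of the arrays were fixed before. Passage 4 and regenerated cells differed in 1912 probe sets by the test of the difference itself, which is what singled out the values that follow. List medians, as passage 4 minus regenerated on the log2 scale, were 0.938 for cell cycle, 1.09 for nuclear factors lost in senescence, and 0.0743 for proteasome genes. They were -0.35 for extracellular matrix, -0.831 for matrix proteases and inhibitors, -0.415 for smooth muscle, -0.911 for fibroblast, -0.723 for cardiac and adipose markers and -0.537 for shear-stress and quiescence regulators. None of these lists passed with an estimated correlation (adjusted p from 0.187 to 0.596), a test on only 6 residual degrees of freedom. The matrix, protease, fibroblast and shear-stress lists did not pass with the kinds of labelling as a block either (0.06, 0.0761, 0.0805 and 0.452).

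Among named genes with a difference past the threshold, the log2 difference was 3.75 for STMN2 (dimmer probe set), 4.90 for ALDH1A1, 3.47 for EPB41L3, 4.29 for WDR1, 4.71 for ACADVL, 2.66 for IL7, 4.04 for GABRA4 and 2.98 for TSPAN7. It was 1.19 for CENPF, 2.65 for TYMS, 2.05 for CCNA2, 0.91 for TOP2A, 1.20 for RPL37, 0.58 for PSME1, 1.24 for PSMF1 and 0.77 for PSMB10. It was 1.48 for DDX58, 2.21 for KRT8, 3.99 for SERPINB2, 2.48 for ADM and 1.26 for HILPDA. Lower at passage 4 were F3 at -4.07, SAA2 at -1.93, SLA-DRA at -2.04, SLA-DQB1 at -2.86, IGFBP2 at -3.96, MMP2 at -1.97, ZFP36 at -1.39 and PPP1R15A at -1.03. Also lower were FABP4 at -3.64, CDKN1A at -0.64, SLC1A1 at -1.69, PMEPA1 at -4.25, MAP2K6 at -3.78, ASPN at -4.49, FNTA at -3.40, FAP at -3.35 and NPPB at -1.91. With the kinds of labelling as a block 35 of these 38 genes did not pass, and TSPAN7, FABP4 and ASPN did. The sign was the same in 37, and DDX58 was at -0.32. With that block WDR1 and ACADVL were at 0.11 and 0.85 (adjusted p = 0.924 and 0.618), and their brightest probe sets were at -0.19 and -0.11 without it. Other probe sets of DDX58, PSMF1, SLC1A1 and SAA2 did not pass, and another of FNTA was higher at passage 4 (1.47). The 28S ribosomal RNA probe set, a control outside the comparisons, was at a mean of 8902 at passage 4 and 3254 at passage 1.

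The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. For passage 4 against passage 1 only 1 split, the real one, gave 733 probe sets or more, and the highest other gave 0. For regenerated against passage 1 the real split gave 840 and the highest other 9, and for passage 4 against regenerated the real split gave 1912 and the highest other 0.

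The surplus of probe sets higher at passage 4 than in regenerated cells may come in part from the kinds of labelling. Passage 1 array 1, labelled like the passage 4 arrays, lay above the mean of the other passage 1 arrays in 69.3% of the 1246 rises, against 53.6% of all tested probe sets, and their median difference went from 1.37 to 0.96 with the block. Rises made up 65.2% of the 1912 calls, or 56.4% with median centring, and in 411 dim probe sets called up while the brightest probe set of the gene was not, passage 1 array 1 lay above in 81.5%. For the 666 falls that array lay below in 49.7%, against 46.4% of all tested, and the median was -1.18 without and -1.17 with the block, which goes against the labelling but rests on that single array. In passage 4 against passage 1 that array lay above the mean of the others in 65.8% of the 415 rises. Their median went from 1.44 to 1.17 with the block. For the 318 falls there it lay above in 53.1%, with medians of -1.45 and -1.5. Rises made up 56.6% of the calls there, or 51% with quantile normalization and 52% with median centring. A culture difference of passage 1 array 1 would look the same, and passage, regeneration, RNA input and later deposit stay open as untested.

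For the higher cell cycle genes at passage 4, the median was 0.886 against passage 1 array 1 alone and 0.70 over all passage 1 arrays, and all 3 passage 4 arrays lay above that array in 49 of 50 genes. This goes against the labelling, but that array is the only passage 1 array of its kind, the other arrays supply the spread, and its own culture state could set the result, so the labelling stays open. A larger share of smooth muscle cells or fibroblasts stays open, as the larger of their list medians was 0.175, over members that went both ways. Against passage 1 array 1 alone the fibroblast median was 0.564 and the smooth muscle median -0.296. Passage itself and differences in growth or density may also contribute, and were not tested.

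For the higher mesenchymal genes in regenerated cells, the labelling is argued against for the matrix and smooth muscle lists, whose medians were 0.397 and 0.722 against the passage 1 arrays of the same labelling and 0.337 and 0.636 against all 3. The fibroblast list was at 0.687 against 1.04, still past the threshold (camera adjusted p = 0.00116), so the labelling may account for part of it. A larger share of smooth muscle cells or fibroblasts cannot be told apart from a change within the endothelial cells. The cells were scraped from the vessel and the labels name no sort. The list of endothelial-to-mesenchymal transition genes and TGF-beta targets did not pass in regenerated cells (median 0.18, camera adjusted p = 0.195). Of the 25 members of those marker lists 22 were higher, with a median of 0.719, but 18 did not pass, among them the fibroblast genes COL1A2 (0.08, SE 0.25) and DCN (0.23, SE 0.48), and TAGLN (-0.04), DPP4 (-0.15) and CDH11 (-0.88) were lower. Regeneration, the culture without passage, RNA input, deposit and the lower 5' signal of the pig's own transcripts could each contribute. They share the same group, the last of them mainly in regenerated arrays 2 and 3.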

How the results depend on the processing

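The fit with the kinds of labelling as a block was chosen after the data were seen, and the other alternatives before. The count for passage 4 against passage 1 (733) was 1793 with array weights and 150 with the labelling block, and ran from 244 to 1403 with 1 array left out. It was 1403 without passage 1 array 1, 244 without passage 1 array 2, and 310, 300 and 262 without passage 4 array 1, 2 or 3. For regenerated against passage 1 (840) it was 479 with only those groups in the fit, and ran from 291 to 1238. It was 513 without passage 1 array 3, 291 without regenerated array 2 and 345 without regenerated array 3. For passage 4 against regenerated (1912) it was 3327 with array weights, 35 with the labelling block, and ran from 895 to 2406. It was 1043, 1033 and 983 without passage 4 array 1, 2 or 3, and 943 and 895 without regenerated array 2 or 3. The number of probe sets past the threshold in both comparisons (197) was 323 with array weights and 71 with the labelling block, and ran from 87 without passage 1 array 2 to 297 without passage 1 array 1. That overlap was 112, 107 and 107 without passage 4 array 1, 2 or 3, and 114 and 124 without regenerated array 2 or 3. The cause was not tested, except that leaving out an array or a group leaves fewer arrays.

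Of 84 list tests 30 passed, and from 28 to 35 did so with 1 array left out, 26 with fry, 25 with the labelling block and 0 with an estimated correlation in camera. The block made 3 other lists pass, which were oxidative stress at passage 4 (adjusted p = 0.0423) and cell cycle (0.0405) and cholesterol synthesis (0.0226) in regenerated cells. Of 112 named gene results 45 were past the threshold without that block and not with it. No result past the threshold had the opposite direction past it under any alternative, but the proteasome median turned sign, to 0.0849 at passage 4 with the labelling block and to -0.00743 for passage 4 against regenerated with median centring. Named gene calls were also lost 127 times when each array was left out in turn. Counting the block, HILPDA lost its call in 16 of 20 alternatives, LUM in 14 of 19, and PPP1R15A and SMTN in 13 of 20. ACADVL at passage 4 lost its call in 13 of 20, NOS3 and TIMP1 in 12 of 20 and SYNM in 10 of 19. Others, such as F3 and EPB41L3 at passage 4, lost it in 0 of 20. The numbers of the replicates showed no sign of pairing the samples. Of 9 pairs of arrays with the same number 1 had deviations correlated over 0.1 (from -0.14 to 0.19). Pairs with other numbers ran from -0.2 to 0.18, and 2 of 9 arrays matched their own number best. With only 3 arrays per group this check cannot exclude a shared animal or batch, which the labels do not settle. With the replicate number as a block the counts were 549, 554 and 1626. Signal near background limits what dim genes can show, as the pseudocount of 16 shrinks their changes.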

Other observations

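Other gene groups did not pass at passage 4. Senescence and p53 targets had a median log2 change of 0.20 (camera adjusted p = 0.109) with 0 of 28 rising and 1 falling, or 3 and 1 adjusted over the list alone, and oxidative phosphorylation genes a median of 0.03 with 0 of 59 past the threshold (adjusted p = 0.242). Vasoactive factors had a median of 0.06 (adjusted p = 0.742) and angiogenic and growth factor signalling -0.22 with 4 of 26 falling, or 5 with 2 rising adjusted over the list alone (adjusted p = 0.135). With fry in place of camera the angiogenic list passed downward (adjusted p = 0.0189). Oxidative stress and antioxidant genes had a median of -0.16 with 3 of 41 rising and 6 falling, or 4 and 7 adjusted over the list alone (adjusted p = 0.124), and passed without passage 1 array 3 (0.0183) and within the kind of labelling (0.0423). Coagulation and fibrinolysis genes had a median of 0.04 and a mean of -0.24, with a downward test (adjusted p = 0.742) and 3 of 18 falling, or 3 with 4 rising adjusted over the list alone. Genes of the endothelial-to-mesenchymal transition had a median of -0.11 and a mean of 0.08 (adjusted p = 0.951). Leukocyte markers had a median of -0.50 with 1 of 8 falling (adjusted p = 0.17), and epithelial and mesothelial markers 0.006 (adjusted p = 0.926). Without passage 1 array 2, senescence and p53 targets (adjusted p = 0.0343), oxidative phosphorylation and leukocyte markers (both 0.0483) passed. With an estimated correlation none of the 28 lists passed in any comparison, the lowest adjusted p being 0.133, 0.136 and 0.187. That test has only 6 residual degrees of freedom, so it does not show that correlation between genes undid the calls.

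In regenerated cells the cell cycle list had a median of -0.22 with 39 of 50 genes lower (adjusted p = 0.101), and cholesterol synthesis genes 0.22 with 14 of 18 higher (adjusted p = 0.101). Neither passed over all 9 arrays. The cell cycle list passed without passage 1 array 1 (adjusted p = 0.0395) or regenerated array 1 (0.00131), as did cholesterol synthesis (0.0229 and 0.0124). Senescence and p53 targets went both ways, with 3 of 28 rising and 3 falling, or 6 and 4 adjusted over the list alone (median 0.07, adjusted p = 0.39). Oxidative stress genes had a median of -0.15 with 4 of 41 falling, or 5 adjusted over the list alone (adjusted p = 0.218), and passed without passage 1 array 3 (0.0322) or regenerated array 3 (0.0434). Ribosomal protein genes were at -0.02 with 0 of 62 past the threshold (adjusted p = 0.708), and passed upward without regenerated array 2 (median 0.13, adjusted p = 0.000462) and downward without regenerated array 3 (-0.13, adjusted p = 0.0116). Nuclear factors lost in senescence were at -0.35 (adjusted p = 0.108), and passed without regenerated array 1 (0.0231). Erythroid and platelet markers, with 4 genes too few to test, had medians of 0.11 at passage 4 and 0.11 in regenerated cells.

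Between passage 4 and regenerated cells, the MHC, ribosomal and coagulation lists did not pass over all 9 arrays but did with some arrays left out. The MHC median was -0.17 (adjusted p = 0.0717), and the list passed without passage 4 array 1 (0.0206). The ribosomal median was 0.08 (adjusted p = 0.134), and the list passed without passage 4 array 2 (0.0146) or regenerated array 3 (6.88e-07). The coagulation and fibrinolysis median was -0.21 (adjusted p = 0.0588), and the list passed without passage 1 array 2 (0.0476), passage 4 array 1 or 2 (0.027 and 0.0146) or regenerated array 2 (0.0339).

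The probe set annotated as P14ARF, a product of the CDKN2A locus that activates p53 signalling, was chosen after its values were seen. Whether it also detects p16, another product of that locus, is not given in the sources used here. The signal of P14ARF rose from 63.4 ± 55.4 at passage 1 to 432 ± 84.4 at passage 4 (SD, n = 3), a log2 change of 2.70 (SE 0.42, adjusted p = 0.00515). In regenerated cells P14ARF was at 272 ± 76.8, a log2 change of 2.04 (adjusted p = 0.0173), and passage 4 and regenerated did not differ past the threshold (0.66, adjusted p = 0.329). Within the kinds of labelling the changes of P14ARF were 3.50 (adjusted p = 0.0131) and 1.65 (adjusted p = 0.0381). IFNB1, for interferon beta, was also chosen after its values were seen and changed by -2.31 (adjusted p = 0.00855) and -2.27 (adjusted p = 0.00762).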
